A study of Homo sapiens with 84 samples.

How the data were processed

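RNA from 84 human meningiomas, tumors of the membranes around the brain, was measured by long-read cDNA sequencing on the PacBio platform (Iso-Seq), in which a read is meant to span a whole transcript. Per the labels' protocols, frozen tumor tissue was lysed mechanically, total RNA was extracted with a column kit, and cDNA was made and amplified with a low-input kit before the sequencing adapters were added. Each library carries its own patient number in the labels. Tumor grade, molecular class, treatment and outcome are not given in the sources used here, so all 84 libraries formed 1 group and no groups were compared.

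The deposited table holds estimated counts per transcript and library, which are not scaled. Per the submitters' processing notes, reads were aligned with minimap2 to hg38. The versions are not given in the sources used here. Per the deposited file's name, transcripts were counted with bambu, which also adds transcripts that the annotation lacks, on GENCODE release 47 and the assembly GRCh38.p14. Any filter that the authors applied to reads is not given in the sources used here. Of the values above 0, 50.3% were fractional, because the counting shares a read between transcripts that it cannot tell apart. Whether 1 count stands for 1 read or for a consensus of several reads is not given in the sources used here. Amplified cDNA was counted without molecular identifiers, so intervals and limits drawn from counts cover counting error only. Of the table's columns, 1 column of values per sample matched no sample in the labels and was not used.

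The table listed 387046 transcripts of 78804 genes, of which 85831 transcripts of 22156 genes had a count. Transcript counts were summed per gene. Gene symbols were matched for 20697 genes, which held 99.6% of the counts, from a table of gene names and the RefSeq gene table on GRCh38.p14, which also gave the coordinates printed here. Transcript names, exon numbers, lengths and GC content came from GENCODE release 29, an older annotation than the authors', and covered 84.5% to 92.1% of the counts of a library. Transcripts without a name there are given by their identifier. Genes on chromosome Y, immunoglobulin and T cell receptor segments, and a fixed list of further genes were left out of every gene table, 124 genes with 0.252% of the counts.

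Library totals ran from 22356 to 135796 counts with a median of 68472, so 1 count stood for 44.7 CPM (counts scaled to the same total in every library) in the smallest library, 14.6 CPM in the median library and 7.36 CPM in the largest. A gene of 10 CPM was thus expected at less than 1 count in the median library. A gene with 0 counts in all libraries could still make up 0.494 CPM, the share that 3 counts of the 6073978 counts of all libraries give. Duplicate deposits were looked for among the 3486 pairs of libraries. No pair was identical (0 pairs). The smallest difference of a pair, as chi-squared per degree of freedom, was 1.14 (median 3.29), and the highest r was 0.866 (median 0.533). A check for identical counts cannot tell whether 2 libraries came from the same tumor. All libraries were kept as separate samples, as the labels number them.

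The scores of gene lists, the pairs of scores to be related, the gene lists themselves and the alternatives were fixed before the data were examined, except where an alternative is said to have been added. There were 24 lists with 307 genes. A list's score was the mean of log2(CPM + 1) over its members with a mean of at least 0.5 CPM. Along the score of 20 proliferation genes and the score of 15 myeloid genes, each standardized over the libraries, counts rounded to whole numbers were tested gene by gene in edgeR 4.0.16 with the quasi-likelihood F test, TMM normalization, the filter filterByExpr and log10 of the library total as covariate. The score's own genes were left out of the test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Changes are given in log2 units per standard deviation (SD) of the score with their standard error (SE). Fixed lists with at least 3 tested genes were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, adjusted over the lists.

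Isoform use along the proliferation score was tested with diffSpliceDGE in edgeR (gene-level F test) over transcripts with at least 5% of the counts of their gene, in genes with a mean of at least 10 counts. The share of a transcript was computed in libraries with at least 10 counts of its gene. Relations between scores were measured as Pearson's r and Spearman's rho, each with a 2-sided permutation test of 100000 resamples, adjusted over the 17 relations computed. Where a mixture of 2 normal distributions described a variable better than 1 by over 10 units of the Bayesian information criterion, with means over 2 root-mean-square SDs apart, r was computed within each cluster. For single genes the lower cluster was the set of libraries with no count. Co-variation of chromosome arms was measured as the SD over libraries of the mean of centred log2(CPM + 1) over the genes on an arm, at a mean of at least 10 CPM. It was set against 10000 random sets of autosomal genes of equal number and matched mean expression, in 39 arms with at least 30 genes. The analysis ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9, and in R 4.3.3 with DESeq2 1.42.0 as an alternative to edgeR.

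The genes named in the text follow a rule fixed in advance. For each score these were the 10 genes with the largest rise and the 10 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 CPM, a symbol and a permutation p under 0.05 for the rank correlation with the score. Up to 4 members, those with the largest and smallest changes, stand for each list that passed. Further, the 10 genes with the highest mean CPM were named, and the 20 with the largest SD of log2(CPM + 1) at a mean of at least 10 CPM. For isoforms the 10 genes with the smallest p and the 10 with the most variable leading isoform were named, together with a list of genes known for alternative splicing. All members of the list of steroid and somatostatin receptors and of the list of genes recurrently altered in meningioma are given as levels. Other genes are named as examples of the levels of a cell type or a list. A few genes that met these rules are not reported here.

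The tests of genes, isoforms, correlations and arms were run on simulated data, and the list tests and the mixtures were not. In counts drawn for the 4100 genes of the proliferation test, 51% of genes given a change of 0.3 log2 units per SD and 94% of those given 0.6 were recovered, and 6.45% of the calls were false. For the 4093 genes of the myeloid test the shares were 64% and 89%, with 7.27% false calls. For isoforms in 1335 genes, 45% of changes of 0.5 log2 units and 93% of changes of 1 were recovered, but 12.7% of the calls were false, over the 5% aimed at. In 100 draws of scores with no relation, 13% of the tests of r gave a p under 0.05 and the median r was 0.0745, where the draws kept the real library totals. With the partial correlation given the library total the share was 2%. A true r of 0.6 was found in 99% of the draws. For arms, a simulated loss of 25% of the expression of the 106 genes of 18q in 40% of the libraries was not called (adjusted p = 0.133), and a loss of 50% was called (adjusted p = 0.0039). With library total and transcript length regressed out of each gene, both were called at an adjusted p of 0.0039, the smallest that the sets allowed. These counts were drawn independently for each gene with a fixed dispersion, and 0 other arms were called. In the real data genes vary together and 29 of 39 arms passed, so the power found here need not hold there.

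The alternatives covered normalization, filters, pseudocounts, covariates, the makeup of the scores, libraries left out, thinning of every library to 22356 counts, other tests and other matching of the random gene sets. Added after the data were seen were scores from pooled counts, corrections for GC content, the isoform test without the libraries of extreme score, and the regression of technical and cell type measures out of the arm values. The reads themselves, the genome sequence and DNA measurements of the tumors were not analysed here.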

Results

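Long-read RNA sequencing was used to measure which genes and which transcript isoforms 84 meningiomas expressed. Meningiomas arise from the arachnoid cells of the meninges and hold blood vessels and macrophages besides tumor cells. Each library came from a separately numbered patient, and the labels place all of them in 1 group, so the questions open to these data concern the spread between tumors. Library totals ran from 22356 to 135796 counts (median 68472). A library held 9152 ± 1369 genes with at least 1 count (mean ± SD, n = 84; range 5954 to 12881) and 4124 ± 1420 with at least 5 counts. The number of genes with a count followed the library total closely (r = 0.914 with log10 of the total). Thinned to 22356 counts, the libraries held 6695 ± 363 genes. A count was present in every library for 1780 genes, and 10069 genes had a mean of at least 10 CPM.

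Libraries differed in more than depth. The count-weighted transcript length was 4716 ± 382 nucleotides and rose with log10 of the library total (r = 0.857, permutation p = 1e-05; rho = 0.859, permutation p = 1e-05, the smallest the resamples allow; r = 0.844 without the 2 libraries farthest from the median total). The score of 14 cytosolic ribosomal protein genes, which have short transcripts, fell with the total (r = -0.861 and rho = -0.864, both with a permutation p of 1e-05; r = -0.844 without those 2 libraries). The count-weighted GC content was 46.2% ± 1.09 and fell with transcript length (r = -0.771). All tests along a score therefore carried the library total as a covariate, and transcript length and GC content entered as alternatives.

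**Figure D1:**
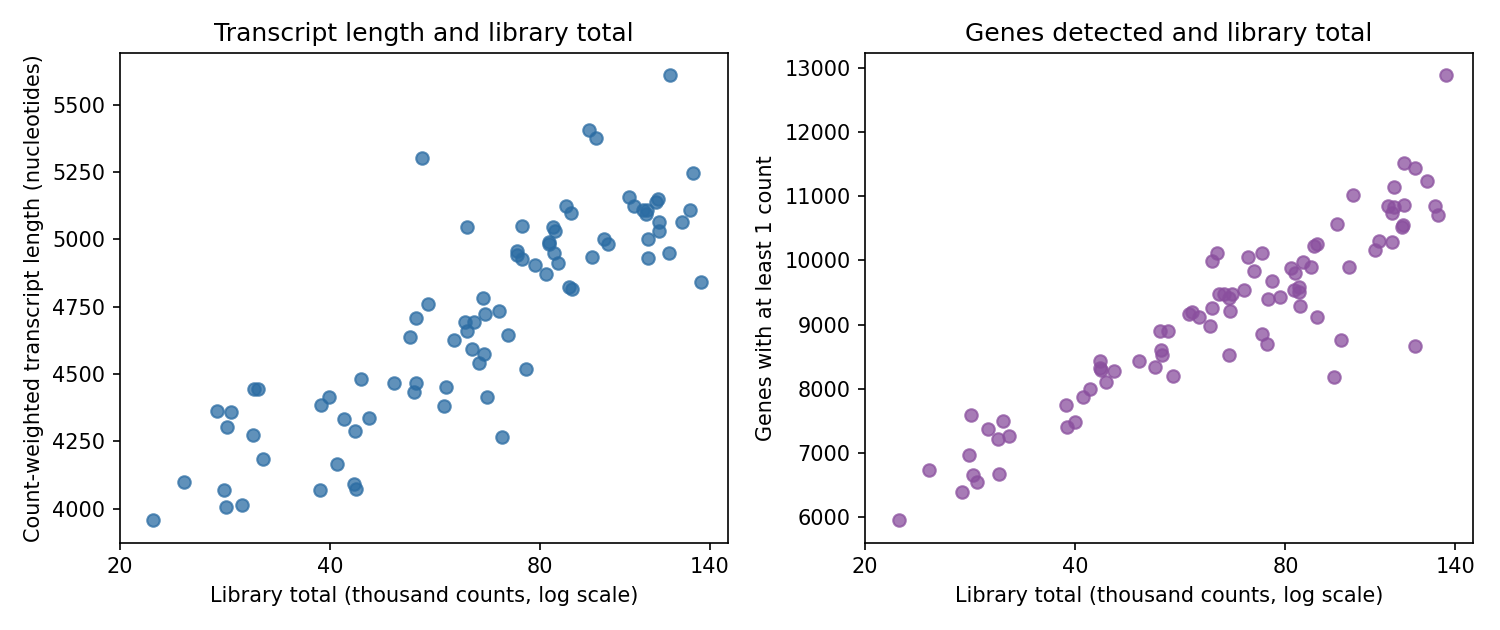
Each point is 1 of the 84 libraries, plotted by its library total on a log axis, against count-weighted transcript length in nucleotides (left) and the number of genes with at least 1 count (right). Both rise with the total, with r = 0.857 for length and r = 0.914 for genes.

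Mean levels over the 84 libraries gave the most abundant genes. This is a ranking by counts, which followed the library total less in short than in long transcripts, as given at the end. Except among the shortest transcripts, they also followed it less in abundant than in rare genes. MALAT1, a long noncoding RNA of nuclear speckles (ENSG00000251562.12, GRCh38.p14 chromosome 11, 65497738 to 65506516), had the highest mean, 6932 ± 6557 CPM (SD, n = 84). FN1, which encodes fibronectin (ENSG00000115414.21, chromosome 2, 215360865 to 215436068), followed at 3683 ± 1967 CPM. The insulin-like growth factor binding protein gene IGFBP5 had 1850 ± 1154 CPM, the type I collagen gene COL1A2 1837 ± 920 CPM, and DSP, which encodes the desmosome protein desmoplakin (chromosome 6, 7541671 to 7586714), 1761 ± 701 CPM. The sulfate transporter gene SLC26A2 had 1638.5 ± 1088 CPM and the mitochondrial ribosomal RNA MT-RNR2 1638 ± 1034 CPM. The RNA-binding protein gene HNRNPK had 1539 ± 277 CPM, the kinase anchor gene AKAP12 1522 ± 791 CPM and the microtubule-associated protein gene MAP1B 1369 ± 713 CPM. Each of the first 9 was counted in every library.

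Of 15 fixed markers of meningeal cells, some were counted in nearly every library and others in far fewer. OGN, which encodes the matrix protein osteoglycin, reached 1151 ± 444 CPM and was counted in 83 of 84 libraries. Vimentin (VIM, 471 ± 265 CPM) and E-cadherin (CDH1, 402 ± 207 CPM) had a count in all 84. The prostaglandin D synthase gene PTGDS had 158 ± 164 CPM in 76 libraries with a count, and the forkhead factor gene FOXC1 174 ± 97.8 CPM in 83. The retinoic acid-forming enzyme gene ALDH1A2 was counted in 40 libraries, with a mean of 63.4 ± 111 CPM.

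Among the receptors used as tissue markers or drug targets in meningioma, the somatostatin receptor gene SSTR2 (chromosome 17, 73165010 to 73176633) was high, at 301 ± 286 CPM with a count in 74 libraries. The progesterone receptor gene PGR (chromosome 11, 101029624 to 101129813) had 158 ± 217 CPM and was counted in 63 libraries, with a median of 4.50 counts. The glucocorticoid receptor gene NR3C1 was counted in all 84 libraries (280 ± 106 CPM) and the mineralocorticoid receptor gene NR3C2 in 61 (81.8 ± 80.8 CPM). Estrogen receptor genes were near the limit of detection, ESR1 at 2.69 ± 7.10 CPM in 14 libraries and ESR2 at 0.514 ± 2.79 CPM in 3. SSTR1 was counted in 4 libraries (2.20 ± 13.3 CPM). SSTR3 and SSTR5 had 0 counts in all libraries, which allows a mean share of up to 0.494 CPM each, from counting error alone.

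Genes that are recurrently altered in meningioma were mostly expressed at a few counts per library. NF2, which encodes the tumor suppressor merlin (ENSG00000186575.20, chromosome 22, 29603556 to 29698600), had 26 ± 35.5 CPM, with a mean of 2.11 counts and a count in 45 libraries. Other genes of chromosome 22 on this list were SMARCB1 (34.4 ± 31.8 CPM), LZTR1 (46.6 ± 30.7 CPM) and CHEK2 (15.6 ± 16.8 CPM). The dystrophin gene DMD had the highest mean of the list (456 ± 429 CPM), followed by the chromatin remodeler gene SMARCE1 (259 ± 76 CPM), PIK3CA (230.0 ± 126 CPM), PBRM1 (214 ± 100.4 CPM) and AKT1 (133 ± 86.1 CPM). Lower levels were measured for POLR2A (92.3 ± 98.8 CPM), BAP1 (64.3 ± 50.9 CPM), KLF4 (63.9 ± 57.2 CPM), SUFU (56.6 ± 44.6 CPM), SMO (52.2 ± 38.7 CPM) and TRAF7 (26.2 ± 30.8 CPM). The cell cycle inhibitor genes CDKN2B (3.04 ± 7.39 CPM, 15 libraries) and CDKN2A (mean 0.142 CPM) were barely counted. TERT had 0 counts, with the same limit of 0.494 CPM.

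Several genes ranged from no count to a high level between tumors. PRG4, which encodes the lubricant proteoglycan lubricin (chromosome 1, 186296273 to 186314567), had 395 ± 681 CPM and no count in 26 libraries. Its SD of log2(CPM + 1) was 4.05. Other variable genes of secreted factors and matrix were POSTN (142 ± 229 CPM), SVEP1 (169 ± 208 CPM), the WNT antagonist gene DKK2 (199 ± 279 CPM) and the growth factor gene FGF7 (106 ± 191 CPM). Among membrane proteins were the anion transporter gene SLC26A7 (124 ± 206 CPM), the natriuretic peptide receptor gene NPR3 (162 ± 222 CPM), the desmosomal cadherin gene DSC3 (113 ± 188 CPM), the integrin gene ITGB4 (168 ± 219 CPM) and the chloride channel gene CLIC5 (95.2 ± 167 CPM). The GTPase family gene RHOBTB3 had 104 ± 176 CPM and the noncoding RNA LINC01088 160 ± 239 CPM. The levels of NBPF19 (133 ± 174 CPM) and PCDHA13 (86.9 ± 97.1 CPM) are uncertain. Both belong to gene families whose members share sequence, and how reads were divided among the members was not examined. A further 5 lie on the mitochondrial genome, where neighbouring genes share precursor transcripts. MT-TS2 was at 0 in 62 libraries and had 24 to 163 counts in the other 22, and MT-TS1 was at 0 in 31. MT-TT was at 0 in 66 libraries, MT-ND6 in 51 and MT-ND3 in 44. How the counting assigned reads that span several of these genes is not given in the sources used here, so their levels are uncertain too.

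Transcripts that the annotation lacked, added by the authors' counting, held 2.38% ± 0.555 of a library's counts (n = 84). The table listed 1387 of them in 80 new and many known genes, and 96.8% of their counts lay in known genes. In several genes such a transcript was the main product. In ABLIM1, an actin-binding LIM protein gene, a new transcript held 73.2% of the gene's counts, was found in all 84 libraries and had a mean of 72.7 ± 42.2 counts, and another new one held 19.7%. New transcripts held 76.6% of the counts of the matrix gene ECM2, 71.1% of those of NDNF, 61.3% of those of the RNA-binding protein gene RBMX and 49.7% of those of NAB1. They held 25% of the counts of IGFBP5, 19.3% of those of SULF1 and 12.3% of those of HNRNPK. These are shares of counts pooled over the libraries, whereas the share of a leading isoform below is a mean of the shares per library. Of the 7081 transcripts with at least 10 counts in at least 2 libraries, 207 were new.

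The leading isoform of a gene was often, but not always, the same in all tumors. Over 67 genes with a mean of at least 50 counts, the leading transcript held a median of 69.3% of the gene's counts (quartiles 43.6% and 91.8%). It held over 90% in 19 genes and under 50% in 23, and it led, alone or tied, in every library in 28 genes. In THSD4, 1 of the 28, the first 2 transcripts had the same share (45.5%), so neither led. The median SD of its share over libraries was 11.5 percentage points. The share moved with library depth, since it was correlated with log10 of the library total in 40 of the 67 genes and with transcript length in 36 (Benjamini-Hochberg adjusted p under 0.05). The share varied most in CEMIP, a hyaluronan-degrading protein gene, where CEMIP-201 held 62.2% ± 33.4 (79 libraries with at least 10 counts). CEMIP-201 still led, alone or tied, in 77 of these libraries, and CEMIP-202 held 20.2%. In IGFBP5 the annotated transcript held 70.4% ± 31 and a new one 29.6%. The proteoglycan gene VCAN followed with VCAN-203 at 40.3% ± 31.1. AKAP12 had AKAP12-201, with 4 exons and 6597 nucleotides, at 51.8% ± 28.1 and AKAP12-204, with 5 exons and 8432 nucleotides, at 38.9%. The former led in 45 of 81 libraries. Next came the kinase gene WNK1 (WNK1-202, 45.7% ± 28.5), the cytokine receptor gene IL6ST (IL6ST-206, 61.4% ± 27.5), OGN (OGN-201, 64.1% ± 25.6), DSP (ENST00000713912.1, 43.1% ± 24.8) and HNRNPU (HNRNPU-205, 66.9% ± 24.6).

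Genes known for alternative splicing showed a strong preference for 1 isoform in some cases and a mixture in others. The cell adhesion gene CD44 was counted almost wholly as CD44-201, the form with 9 exons, at 92.7% ± 17.8 in 47 libraries, with 5.21% in CD44-208, which has 18 exons. PTGDS-202 held 98.0% ± 7.19 (28 libraries), ACTN1-201 81.9% ± 19 (10), ENAH-203 80.6% ± 14 (80), RAC1-201 76% ± 25.7 (77) and TPM3-212 72.7% ± 12 (83). In the pyruvate kinase gene PKM, PKM-202 held 61% ± 10.1 in 82 libraries and a new transcript 33.6%. FN1 was spread over 10 transcripts of at least 5%, of which ENST00000443816.5 led with 16% ± 6.38 (84 libraries). MCL1, an apoptosis regulator, was divided between MCL1-202 (51.8% ± 19.7) and the noncoding MCL1-203 (46.3%), and the tenascin gene TNC between TNC-211 (48.4% ± 25.6) and TNC-202 (44.3%) in 17 libraries. Mixtures were also measured for EXOC7 (EXOC7-201, 59.8% ± 14.3), CDC42 (ENST00000656825.1, 58.5% ± 18.2), LMNA (LMNA-206, 52.4% ± 14.8), MYL6 (MYL6-218, 46.9% ± 22.1), TPM2 (TPM2-203, 41.1% ± 7.85), BCL2L1 (BCL2L1-203, 40.7% ± 10), CALD1 (CALD1-202, 39.8% ± 17.4), TPM1 (TPM1-224, 37.9% ± 16.3), NUMB (NUMB-211, 32.4% ± 9.98), CTNND1 (CTNND1-201, 26.1% ± 15.9) and FGFR1 (FGFR1-206, 20.1% ± 20.2). In VEGFA, 6 transcripts had about equal shares in 13 libraries (VEGFA-204, 16.6% ± 0.171), so the counting did not tell them apart. NF2 reached 10 counts in 4 libraries, too few for a statement on its isoforms.

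In tumors with a higher proliferation score THBS2, OAS3 and BCAT1 were among the genes with higher levels, and ACADL and LEPR among those with lower levels. The score was the mean log2 level of 20 cell division genes, led by TOP2A (94.7 ± 157 CPM, 65 libraries with a count) and NUSAP1 (61.9 ± 71.8 CPM, 72 libraries). MKI67 had 27.2 ± 93.7 CPM and a count in 38 libraries. The score rested on a median of 17 counts per library. Per SD of the score, THBS2, which encodes the matrix protein thrombospondin-2 (ENSG00000186340.17), rose by 1.19 ± 0.18 log2 units (SE; mean 73.1 CPM; adjusted p = 4.3e-06; rho = 0.483). Other matrix and basement membrane genes that rose were the laminin gene LAMB3 (1.09 ± 0.29, adjusted p = 0.0109), the aggrecan-cleaving protease gene ADAMTS5 (0.96 ± 0.21, adjusted p = 0.00143), the periostin gene POSTN (0.82 ± 0.21, adjusted p = 0.00703) and COL15A1 (0.68 ± 0.16, adjusted p = 0.00413). OAS3, an interferon-induced sensor of double-stranded RNA, rose by 1.01 ± 0.16 (adjusted p = 4.1e-06; rho = 0.590). The mechanically gated channel gene PIEZO2 (0.81 ± 0.20), the semaphorin gene SEMA5A (0.78 ± 0.18), the branched-chain amino acid transaminase gene BCAT1 (0.75 ± 0.11, adjusted p = 5.9e-07) and the retinol dehydrogenase gene RDH10 (0.70 ± 0.16) rose as well.

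Genes that fell along the proliferation score included ACADL, a fatty acid oxidation enzyme gene (-1.17 ± 0.27 log2 units per SD, adjusted p = 0.003). The leptin receptor gene LEPR, the most abundant of them at 1029 ± 593 CPM, fell by 0.69 ± 0.11 (adjusted p = 1.2e-05; rho = -0.464). PRG4 (-1.06 ± 0.31), PTCHD4 (-0.87 ± 0.26), the transcription factor gene EBF1 (-0.83 ± 0.19), the methyltransferase gene INMT (-0.69 ± 0.22), the growth factor gene PDGFD (-0.66 ± 0.14), the lysine-degrading enzyme gene AASS (-0.65 ± 0.15) and the apolipoprotein gene APOD (-0.65 ± 0.18) also fell, with adjusted p from 0.000987 to 0.0388. Their rank correlations with the score ran from -0.411 for PDGFD to -0.264 for PTCHD4.

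In all, 346 of 4100 tested genes passed, 205 higher and 141 lower, and 913 had a p under 0.05. DESeq2 called 378 proliferation gradient genes with another division, 174 higher and 204 lower. The count depended on the libraries at the ends of the score. Without the 2 highest and 2 lowest scores 86 genes passed, 79 of them among the 346, and without the libraries with the lowest totals 169 passed. Of the named genes, POSTN, SEMA5A, BCAT1, PRG4 and INMT did not pass without the 4 libraries at the ends. LAMB3, RDH10, COL15A1 and PTCHD4 did not reach the filter for counts there and were not tested.

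Of 18 fixed lists tested along the proliferation score, 5 passed with camera's preset correlation. None of the 5 passed when the correlation within each list was estimated (0 of 18 lists). Interferon response genes were higher (adjusted p = 0.0193; adjusted p = 0.378 with an estimated correlation), with 2 of 6 members passing over all genes tested and 5 adjusted over the list alone. IFIT2, an interferon-induced RNA-binding protein gene, rose by 0.39 ± 0.11, whereas MX1 changed by 0.17 ± 0.11 and did not pass. DNA replication genes were higher (adjusted p = 0.0339; adjusted p = 0.315 with an estimated correlation), with 2 of 3 members passing over all genes and 2 adjusted over the list alone, the helicase subunit genes MCM7 (0.37 ± 0.10) and MCM3 (0.16 ± 0.05). Extracellular matrix genes were higher (adjusted p = 0.0339; adjusted p = 0.496 with an estimated correlation). Here 4 of 12 members rose, and 5 adjusted over the list alone. They included POSTN, COL6A3 (0.49 ± 0.14) and COL5A1 (0.48 ± 0.16), while FN1 (0.02 ± 0.10) and DCN (-0.15 ± 0.14) did not pass. Mural cell genes were lower (adjusted p = 0.0344; adjusted p = 0.315 with an estimated correlation), with the pericyte gene RGS5 (-0.35 ± 0.09) as the only 1 of 5 members to fall, both over all genes and adjusted over the list alone. Immediate early genes were lower (adjusted p = 0.0339; adjusted p = 0.496 with an estimated correlation), although 0 of 6 members passed, over all genes or adjusted over the list alone. The values were -0.43 ± 0.21 for EGR1 and -0.13 ± 0.05 for BTG2. The other lists had adjusted p from 0.0993 for cytosolic ribosomal proteins to 0.944 for genes recurrently altered in meningioma. Among those were meningeal and meningioma markers, with 0 of 12 members passing.

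**Figure D2:**
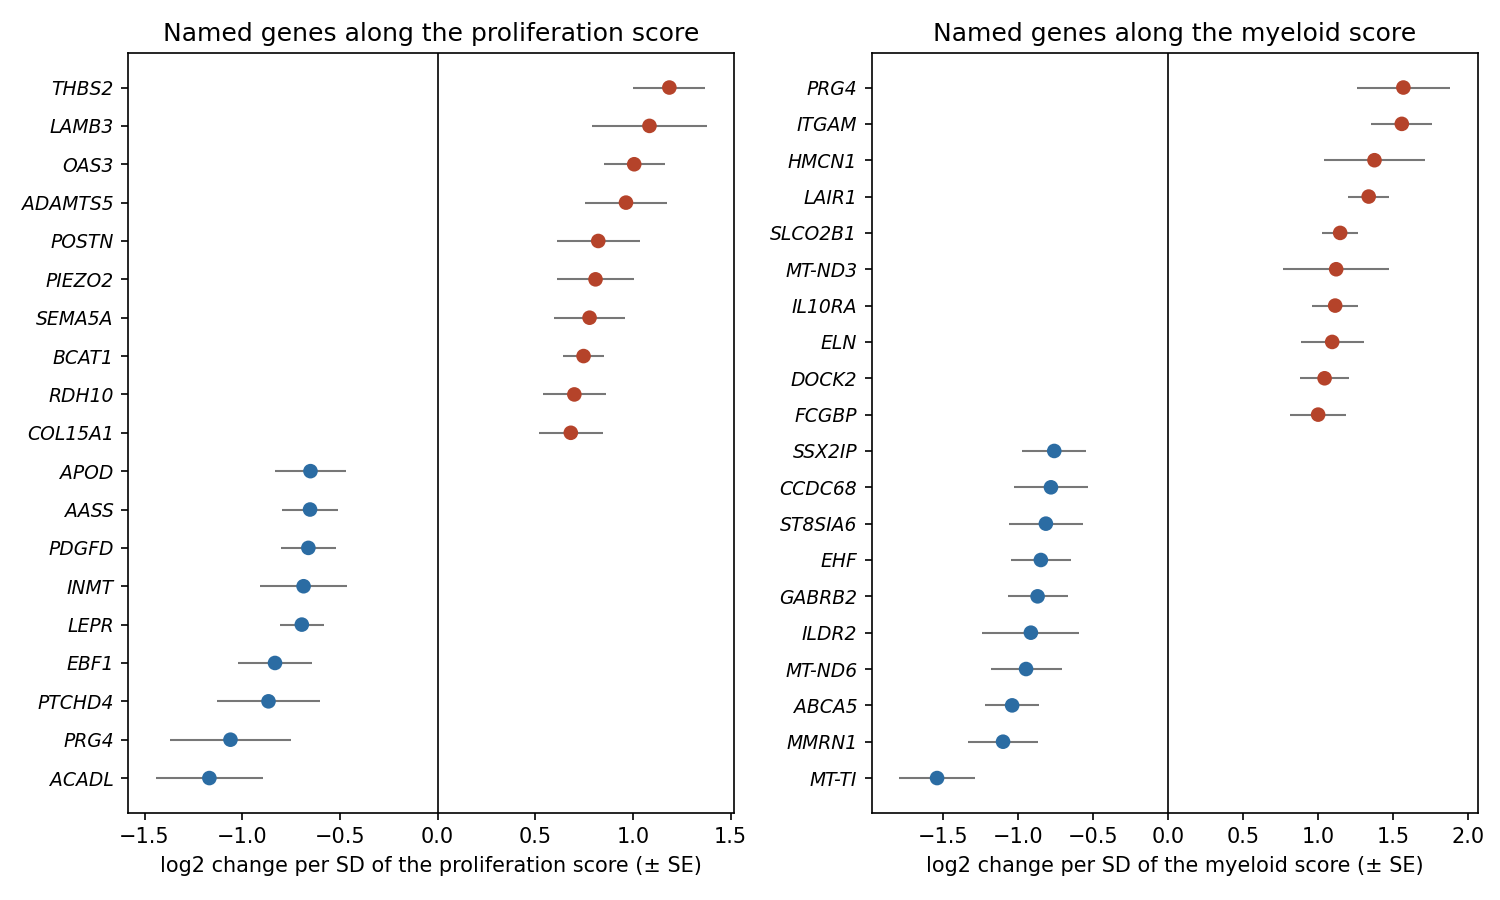
Points are fitted changes in log2 units per SD of the proliferation score (left) and of the myeloid score (right) for the named genes over 84 libraries, and bars are standard errors, with genes that rose in red and genes that fell in blue. THBS2 rose most along proliferation (1.19) and ACADL fell by 1.17, while PRG4 rose most along the myeloid score (1.57) and MT-TI fell most (-1.54).

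Isoform use changed along the proliferation score in few genes. Of 1335 genes with 3944 transcripts, 16 passed and 186 had a p under 0.05. Of 20 shuffled scores, the highest gave 8 genes and the median was 0. In the cytoskeletal gene ADD3, ADD3-202, which has 15 exons, went from a fitted share of 4.81% at 1 SD below the mean score to 16.3% at 1 SD above, and ADD3-201, which has 14, from 77.3% to 65.5% (adjusted p = 8.1e-05; 80 libraries; rho = 0.329 for ADD3-202). In MATR3, an RNA-binding protein gene, a transcript with a retained intron, ENST00000505625.5, went from 17.3% to 5.61% (adjusted p = 0.00621; rho = -0.465, permutation p = 0.0001, the smallest the resamples allow). In RB1, the retinoblastoma tumor suppressor gene, RB1-202, a short transcript annotated for nonsense-mediated decay, went from 10.7% to 1.44% (adjusted p = 0.0046; rho = -0.366). The fatty acid activating enzyme gene ACSL1 had the smallest p (adjusted p = 5.7e-05), with ENST00000706366.1 going from 2.56% to 12.8% in 38 libraries. POGZ-204 went from 3.39% to 9.82% (adjusted p = 0.00853). The other POGZ transcripts, POGZ-201 and ENST00000710270.1, had identical shares, so they were not told apart. Shares went down for NUP153-202 (23.6% to 4.46%, adjusted p = 0.00907), BCLAF1-223 (14.1% to 5.003%, adjusted p = 0.0154) and ENST00000699328.1 of NFE2L2 (19.6% to 5.24%, adjusted p = 0.0046), although the rank correlation of the last was -0.141. MBP-202 went from 5.39% to 32.8% in the fit (adjusted p = 0.0046), but its rank correlation was 0.0934 over 36 libraries, so the myelin basic protein gene MBP is not a firm call. With Simes' test 5 genes passed, and with a minimum share of 10% per transcript 6 passed.

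Tumors with a higher myeloid score had higher levels of MHC class II genes and of single genes such as LAIR1 and ITGAM. The score was the mean log2 level of 15 macrophage-lineage genes, led by the scavenger receptor gene CD163 (521 ± 362 CPM, counted in all 84 libraries), the growth factor receptor gene CSF1R (251 ± 120 CPM, 83 libraries) and the mannose receptor gene MRC1 (185 ± 151 CPM, 75 libraries). Per SD of the score, the leukocyte integrin gene ITGAM rose by 1.56 ± 0.20 log2 units (SE; mean 42.3 CPM; adjusted p = 1.7e-08; rho = 0.479). LAIR1, an inhibitory collagen receptor gene of leukocytes, rose by 1.34 ± 0.14 (adjusted p = 7.8e-12; rho = 0.676), the organic anion transporter gene SLCO2B1 by 1.15 ± 0.12 (adjusted p = 1.4e-11; rho = 0.639), the interleukin-10 receptor gene IL10RA by 1.11 ± 0.15 and DOCK2, a leukocyte migration gene, by 1.04 ± 0.16. FCGBP, which encodes an immunoglobulin-binding secreted protein, rose by 1.0 ± 0.19. PRG4 rose by 1.57 ± 0.31 (adjusted p = 0.000222), the hemicentin gene HMCN1 by 1.38 ± 0.34 and the elastin gene ELN by 1.09 ± 0.21 (rho = 0.543). MT-ND3 rose by 1.12 ± 0.35 (adjusted p = 0.0245), with the doubt about its counts given above.

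Lower along the myeloid score were MMRN1, a gene of a secreted endothelial and platelet protein (-1.10 ± 0.23, adjusted p = 0.000624), the lipid transporter gene ABCA5 (-1.04 ± 0.18, adjusted p = 1.7e-05; rho = -0.484), ILDR2 (-0.91 ± 0.32), the GABA receptor subunit gene GABRB2 (-0.87 ± 0.20), the epithelial ETS factor gene EHF (-0.85 ± 0.20; rho = -0.540), the sialyltransferase gene ST8SIA6 (-0.81 ± 0.25), CCDC68 (-0.78 ± 0.25) and the centrosomal gene SSX2IP (-0.76 ± 0.21). MT-ND6 (-0.94 ± 0.24) and the transfer RNA gene MT-TI (-1.54 ± 0.25) were lower as well. MT-TI had 36 to 157 counts in 9 libraries and 0 in the other 75, so its call rests on those 9.

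In all, 601 of 4093 tested genes passed along the myeloid score, 325 higher and 276 lower, and 1219 had a p under 0.05. With transcript length as a further covariate 245 passed (168 higher and 77 lower), 197 of them among the 601, and with the score taken from pooled counts 212 passed. Of 17 fixed lists, 2 passed. All 5 tested MHC class II genes, which present antigen, rose over all genes tested and adjusted over the list alone (adjusted p = 3.3e-12; adjusted p = 0.00057 with an estimated correlation), from 0.43 ± 0.09 for HLA-DMA and 0.45 ± 0.06 for HLA-DRA to 0.60 ± 0.08 for HLA-DPA1 and 0.86 ± 0.09 for HLA-DPB1. Extracellular matrix genes were higher (adjusted p = 0.00364; adjusted p = 0.694 with an estimated correlation), with 5 of 12 members passing over all genes and 6 adjusted over the list alone. These included COL5A1 (0.51 ± 0.17), COL6A3 (0.42 ± 0.15) and FN1 (0.29 ± 0.09), whereas POSTN (-0.09 ± 0.22) did not pass. Mural cell genes did not pass as a list (adjusted p = 0.114), although the pericyte receptor gene PDGFRB rose by 0.47 ± 0.10 and TAGLN by 0.32 ± 0.11, 2 of 5 members over all genes and adjusted over the list alone.

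The 16 fixed pairs of scores asked which cell types and programs varied together between tumors. The myeloid score was higher where MHC class II genes were higher (r = 0.770, rho = 0.702; n = 84) and where T and NK cell genes were higher (r = 0.522, rho = 0.535). The proliferation score was higher where DNA replication genes were higher (r = 0.695, rho = 0.661). These 6 values each had an adjusted permutation p of 5.7e-05, from a raw p of 1e-05, the smallest the resamples allow. Without the 2 libraries farthest from the median of the first score r was 0.778, 0.523 and 0.668. The T and NK cell list had a median of only 3 counts per library, so its score carried large counting error. For that pair r ran from 0.469 to 0.632 over the alternatives. Endothelial and mural cell genes rose together (r = 0.356, p = 0.00075, adjusted p = 0.00319; rho = 0.298, p = 0.00615, adjusted p = 0.0195; r = 0.311 without 2 libraries). The myeloid and extracellular matrix scores were related (r = 0.311, p = 0.00411, adjusted p = 0.014; rho = 0.406, p = 0.00013, adjusted p = 0.000553; r = 0.385 without 2 libraries). That pair did not pass in the 42 libraries with the lowest totals (r = 0.171, against 0.614 in the others) or in the partial correlation given library total, transcript length and GC content (r = 0.211, adjusted p = 0.106). Among the 45 libraries with a count of NF2, its level was higher where the other genes of 22q were higher (r = 0.386, p = 0.0091, adjusted p = 0.0258; rho = 0.363, p = 0.0144, adjusted p = 0.035; r = 0.402 without 2 libraries), though not among those with the lower totals (r = 0.2996). The other 39 libraries had no count of NF2.

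The remaining pairs did not pass by r, except 1p in 1 of its 2 clusters, and by rho proliferation with myeloid genes passed too. By r that pair passed in 0 of 14 alternatives. Its r was -0.0361 in the libraries with the higher totals. Its partial r given library total was -0.216 (adjusted permutation p = 0.0821). For proliferation r was -0.236 with myeloid genes (adjusted p = 0.0521; rho = -0.261, adjusted p = 0.0358), -0.237 with meningeal markers (adjusted p = 0.0521; rho = -0.191, adjusted p = 0.132), 0.155 with T and NK cell genes (adjusted p = 0.207; rho = -0.0540), 0.0552 with hypoxia genes (adjusted p = 0.619; rho = -0.0218) and 0.0560 with the 22q score (adjusted p = 0.619; rho = 0.0163). It was 0.0921 with PGR in the 63 libraries with a count (adjusted p = 0.574; rho = 0.177) and -0.0788 with SSTR2 in the 74 with a count (adjusted p = 0.574; rho = -0.0177). These values leave out the libraries without a count. In the edgeR test over all 84 libraries PGR changed by -0.50 ± 0.25 log2 units per SD (SE; adjusted p = 0.211). SSTR2 changed by 0.11 ± 0.17 in that test (adjusted p = 0.747), so both had the opposite sign and neither passed. The score of 533 genes of 1p fell into 2 clusters, so r was taken within each. It was -0.321 in 46 libraries (adjusted p = 0.0521; rho = -0.257; r = -0.249 without 2 libraries) and 0.383 in the other 38 (p = 0.0182, adjusted p = 0.0443; rho = 0.435, adjusted p = 0.0195; r = 0.407 without 2 libraries). The latter, in the cluster with the lower 1p score, passed and had the opposite sign. The alternatives and partial correlations were run in the larger cluster only, so the latter was not checked against library total. Whether proliferation differed between the 2 clusters was not tested. The values of r within them cannot show it, because each cluster covers only part of the range of the 1p score. For myeloid and interferon response genes r was 0.215 (adjusted p = 0.0696; rho = 0.232), and for endothelial and hypoxia genes 0.223 (adjusted p = 0.0646; rho = 0.171). Both passed in the partial correlation given the library total (r = 0.273 and r = 0.330).

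**Figure D3:**
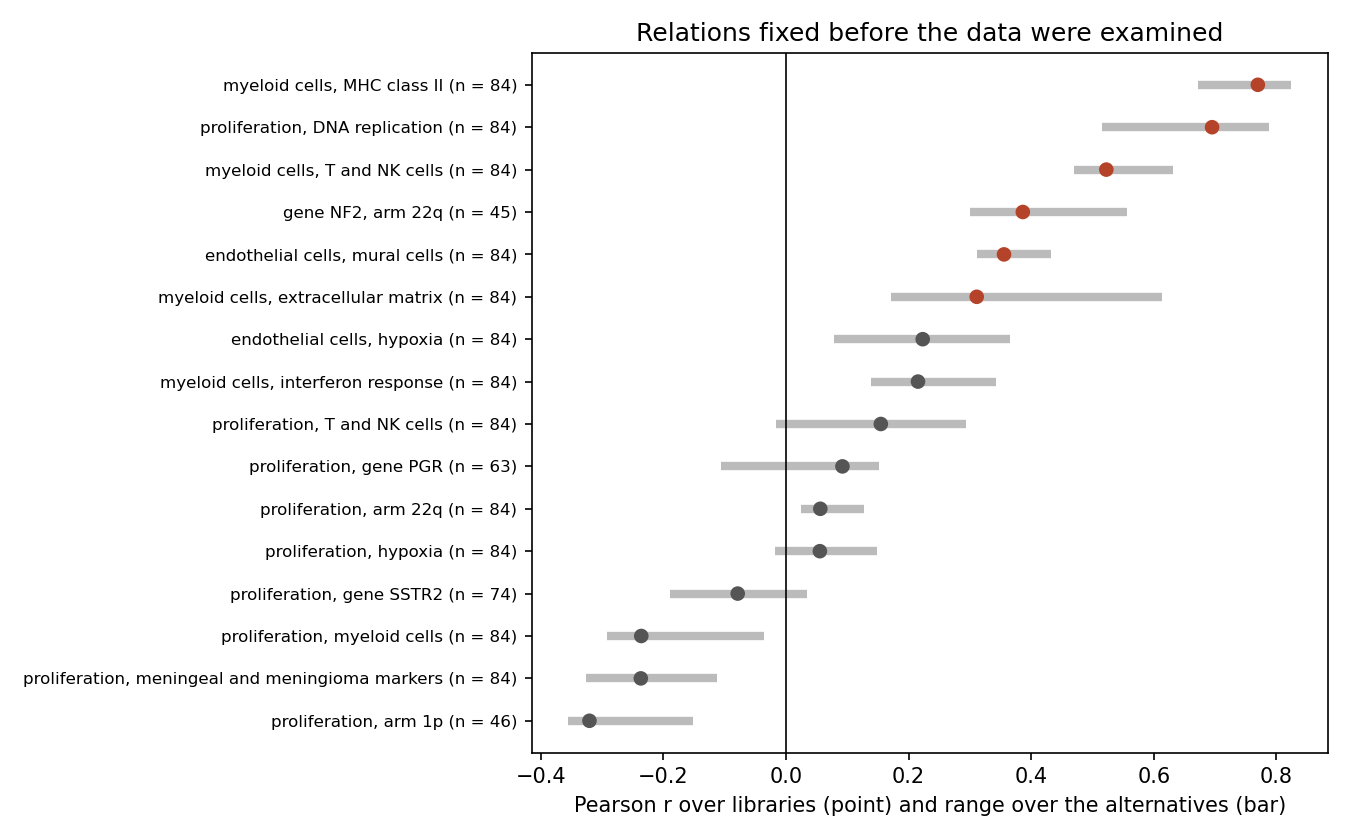
Points are Pearson's r over libraries for the 16 pairs of scores or genes fixed in advance, in red where the adjusted p was under 0.05, and grey bars span r over the alternatives. Where a variable formed clusters the point is that of the larger cluster, with its number of libraries, and the highest r was that of myeloid and MHC class II genes (0.770).

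Whole-arm or partial losses of chromosomes such as 22q and 1p are well known in meningioma, so the genes of each chromosome arm were asked whether their levels moved together between tumors. They did on most arms. Over 84 libraries, the mean of 190 genes on 22q had an SD of 0.77 log2 units, against a median of 0.47 for random sets matched on mean expression, a ratio of 1.63. The highest SD of 10000 random sets was 0.60. The ratio was 1.79 for 106 genes of 18q, 1.74 for 201 genes of 19p, 1.67 for 237 genes of 6q, 1.63 for 285 genes of 4q, 1.54 for 339 genes of 14q and 1.38 for 546 genes of 1p. Each of these had a permutation p of 0.0001, the smallest the sets allow, and an adjusted p of 0.000325. In all 29 of 39 arms passed. The lowest ratio was 0.899, for 419 genes of 12q, which did not pass.

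The order of the arms by this ratio changed when technical differences between libraries were regressed out. With library total, transcript length and GC content regressed out of each gene, and random genes matched on GC content as well, the ratio was 2.77 for 1p and for 6q, 2.70 for 14q, 2.35 for 18q and 2.16 for 3p. It was 1.98 for 22q, 1.497 for 19p and 1.30 for 16p, arms whose genes have a high mean GC content (54.1%, 55.7% and 53.5%). All 39 arms passed in that setting. The ratio also depends on the number of genes, since the mean of a larger random set varies less. It therefore does not rank the arms by how far they moved. With the same corrections, the SD of the arm score relative to all autosomal genes was 0.345 for 1p and 0.385 for 6q. It was 0.390 for 22q, 0.410 for 14q and 0.462 for 18q, so 1p had the lowest SD of these arms.

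**Figure D4:**
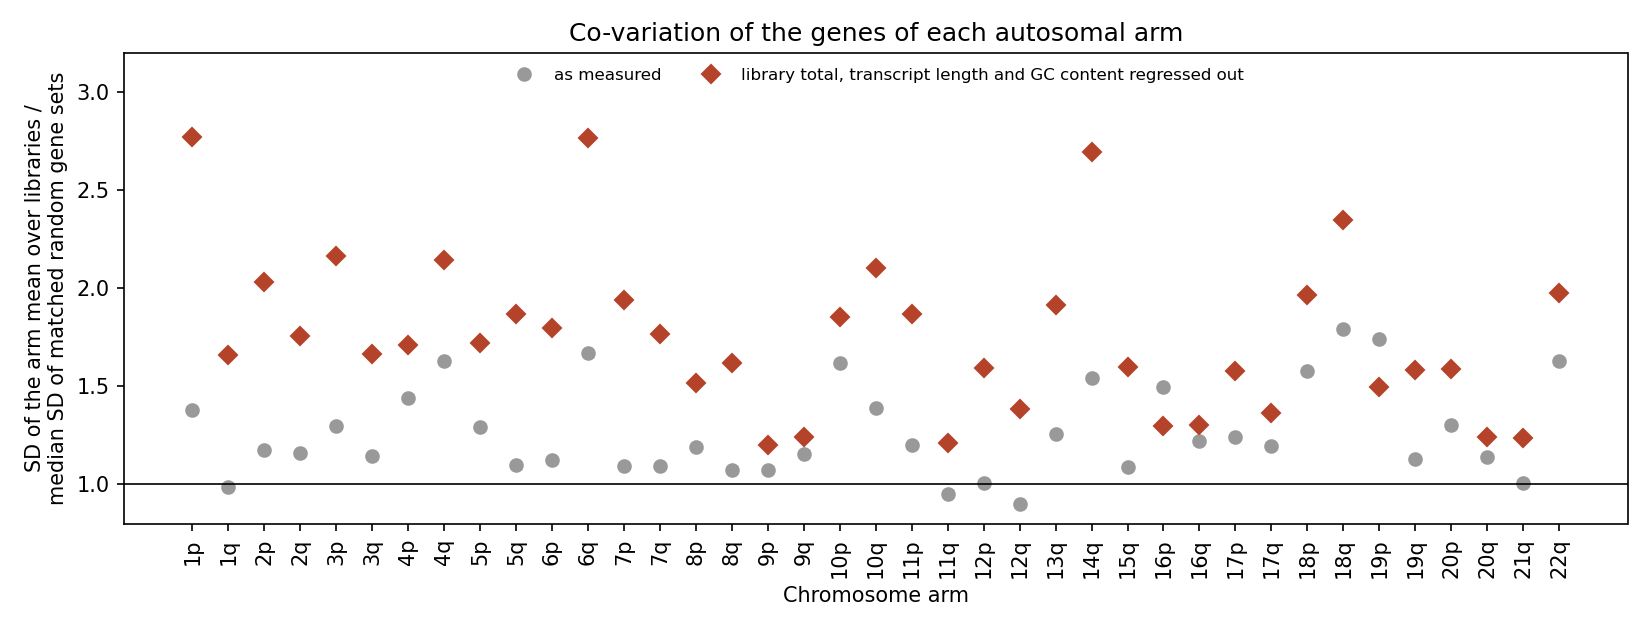
Each autosomal arm is plotted by the ratio of the SD over 84 libraries of the mean level of its genes to the median SD of 10000 matched random gene sets, as measured (grey circles) and with library total, transcript length and GC content regressed out (red diamonds). After that correction 1p, 6q and 14q lie highest (2.77, 2.77 and 2.70), and the line marks a ratio of 1. The ratio also depends on the number of genes of an arm.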

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

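The scores from pooled counts, all corrections for GC content, all corrections of the arms, the joint partial correlations and the isoform test without extreme scores were chosen after results were seen. No named gene turned its direction under an alternative (0 reversed). Of the pairs of scores, 4 that did not pass had the opposite sign in 9 alternative results. For proliferation with PGR, main r 0.0921, r was -0.0297 given library total, -0.0306 with transcript length added, -0.0307 with GC content added and -0.105 in the libraries with higher totals. For SSTR2, main r -0.0788, it was 0.0340 in those with lower totals and 0.0161 without the 2 farthest libraries. For hypoxia, main r 0.0552, it was -0.0184 in those with higher totals and -0.00574 without the 2 farthest, and for T and NK cells, main r 0.155, -0.0158 without the 2 farthest. Over 39 chromosome arms, 235 of 273 alternative results stayed on their side of the threshold, 7 were weaker and 31 stronger, and 28 to 39 arms passed against 29. Over the 16 pairs of scores the numbers were 197 of 224, 3 weaker and 15 stronger besides those 9, and 4 to 8 pairs passed against 6. For the 20 genes that met the naming rule along the proliferation score 213 of 232 held and 19 were weaker, and for the 20 along the myeloid score 206 of 231 held and 25 were weaker. A gene below the filter in a setting has no value there. The cause was not tested where a value below differs from the main one, unless the setting itself changes the number of genes or libraries.

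Genes per library came to 4124 at 5 or more counts and 6695 in thinned libraries, and the share of new transcripts was 1.71% among transcripts with at least 10 counts in at least 2 libraries. The median share of the leading isoform was 28.3% over the 2 genes with a mean of at least 200 counts. Along the proliferation score 961 genes were called with no filter (266 of them among the 346), 169 without the libraries with the lowest totals and 86 without the 2 highest and 2 lowest scores. DESeq2 (174 higher, 204 lower) and transcript length as a covariate (163 higher, 212 lower) moved the balance of the calls, against 205 higher and 141 lower. Lists called along that score were 0 with an estimated correlation. With fry, another list test, extracellular matrix genes did not pass along it (adjusted p = 0.0837). Steroid and somatostatin receptor genes passed with fry as lower (adjusted p = 0.00848), and the other lists called in the main test stayed called. Along the myeloid score 1 list passed with an estimated correlation and 4 with fry. The genes called along it were 2004 with no filter, 245 with transcript length as a covariate, 284 with length and GC content, and 212 with the pooled score. Genes with changed isoform use, 16 in the main test, were 5 with Simes' test, 131 with transcripts of at least 1%, 6 with transcripts of at least 10%, 26 with transcript length and 46 with cell type scores as covariates. Without the 2 highest and 2 lowest scores they were 21, with 13 of the 16 among them. The proliferation score rested on a median of 17 counts and NF2 on a mean of 2.11, so both were measured with large counting error. No paired analysis was possible because every library has a patient number of its own and there is 1 group.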

Other observations

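Besides tumor cells and macrophages, the tumors held transcripts of vessel cells, and some held transcripts of genes on the glial and neuronal list. The endothelial genes PECAM1 (224 ± 146 CPM, SD, n = 84), VWF (195 ± 144 CPM) and KDR, a VEGF receptor gene (118 ± 127 CPM), and the mural cell genes RGS5 (513 ± 267 CPM), PDGFRB (239 ± 132 CPM) and TAGLN (232 ± 166 CPM) were well above the limit of detection. Genes of that list varied more, with MBP at 178 ± 246 CPM, GAP43 at 78 ± 74.1 CPM and the astrocyte gene GFAP at 30.9 ± 115 CPM. MBP was counted in 79 libraries and GAP43 in 68, but GFAP in 13, AQP4 in 8 and SNAP25 in 8. Of the MBP counts tested for isoform use, 82.7% lay in MBP-205 (4 exons) and 17.3% in MBP-202 (9 exons). Whether the MBP counts came from myelin or from other cells was not tested. Lymphoid cells were near the limit. The T and NK cell list had a median summed count of 3 per library (IL32 26.8 ± 60.7 CPM, CCL5 23 ± 29.4 CPM, CD3E 7.11 ± 10.6 CPM) and the B and plasma cell list of 0 (JCHAIN 6.78 ± 15.2 CPM). The mast cell list had a median of 4 counts (KIT 77.9 ± 80.2 CPM, TPSAB1 4.21 ± 19.8 CPM) and the red blood cell list of 1 (HBB 10.96 ± 11.8 CPM).

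Among hypoxia genes the glycolytic enzyme gene PGK1 had 274 ± 119 CPM, the collagen hydroxylase gene P4HA1 218 ± 78.2 CPM, NDRG1 189 ± 93.9 CPM and VEGFA 64.4 ± 88.8 CPM. The chaperone genes HSP90AA1 (590 ± 255 CPM) and HSPD1 (338 ± 163 CPM) were abundant. Merlin acts on the Hippo pathway, and of its target genes AMOTL2 had 277 ± 163 CPM, AMOTL1 224 ± 121 CPM and CCN2 193.5 ± 109 CPM.

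The test of count variation given last was chosen after that pattern was seen, and the test of GC content was added after other results were seen. Of the 346 genes called along the proliferation score, 269 stayed called in the same direction with 5 cell type scores as covariates. These were the myeloid, endothelial, mural, glial and red blood cell scores. With transcript length added as a covariate 286 stayed called, and the library total was already a covariate in the main test. Of 51 orders of the score, the real one included, 1 reached 346 calls, and the highest of the others gave 2. For the myeloid score likewise 1 of 51 orders reached the count, and the highest of the others gave 6. With transcript length as a covariate most calls along the myeloid score did not stay called, as given above. Transcript length was thus not excluded as an explanation for that score. Chance orders and transcript length thus did not account for most of the calls along the proliferation score. The same held for those 5 cell type scores as measured here. The red blood cell list and the glial and neuronal list had a median of 1 and 19 counts per library. T and NK cell genes were not entered, so cell composition was not excluded. No biological explanation was tested because the labels give 1 group.

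The genes of 22q moved together beyond each technical explanation that was tested. The SD of their mean was 0.535 with library total and transcript length regressed out, against 0.245 for the 95th percentile and 0.303 for the highest of the random sets. With the median of the genes in place of the mean it was 0.708 (highest random set 0.586), and with cell type scores regressed out 0.651 (highest 0.508). With GC content regressed out as well and random genes matched on it, the SD was 0.381 (highest 0.260), so part of the movement could stem from GC content. Loss of 22q in some tumors stays open, since other arms moved as much and DNA was not analysed here. The 22q score formed no clusters (BIC gain -13.1, and -2.22 with these corrections), against 22.5 and 15.6 for 1p. With these corrections 6q formed clusters (19.35), but 14q and 18q formed none (1.67 and -5.18). The mixtures were not run on simulated losses, so the lack of clusters cannot decide the question.

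Some counts varied less between libraries than counting of independent reads allows. Among 4238 genes with a mean of at least 5 counts, 64 had a variance below the mean at a lower-tail p under 0.001, against at most 9 in 100 Poisson draws, and RPL6 ran from 4 to 9 counts in libraries whose totals differ 6.07 times. Counts followed the library total more steeply for long transcripts, with a median slope of 0.496 in the shortest of 5 classes of length and 1.44 in the longest. The shortest class held 200 of the 252 genes with a variance below the mean. The draws had a constant mean per gene, so counts that do not follow the library total are no explanation by themselves, and what limited the counts stays open.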
